A study of Homo sapiens with 6 samples.

How the data were processed

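Polyadenylated RNA of 6 SET-2 cell samples was measured by short-read sequencing, 3 samples labelled as placebo (control) and 3 treated with CPL. Per the labels' protocols, total RNA was extracted with TRIzol, 1 µg entered an Illumina TruSeq preparation with oligo(dT) beads and random-hexamer priming, and single-end reads were made on a DNBSEQ instrument. The labels do not state that strand was kept. Groups and replicate numbers came from the sample titles, and the columns of the deposited table were matched to samples by the description field of each sample. No column of other samples was in use (0 such value columns).

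The authors deposited 1 table of FPKM values for 30735 genes and 6 libraries. No header or label names the unit. It was taken from the values: each low value multiplied by the gene's merged exon length in GENCODE 29 was a whole multiple of 1 step per library. Of the values worth up to 20 reads, 98.7% to 99.0% per library were whole within 0.1 of a read. Per the submitters' processing notes, the GRCh38 build and the tools HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 were used by the authors, with no role stated for each, so the step that made the FPKM values is not given in the sources used here. FPKM divides by the library total, so a few abundant genes can lower all others. Gene IDs were looked up in GENCODE 29 on GRCh38, where 30683 of the 30735 were found and 30197 had the position that the table gives. Positions are those of the table.

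The design written before the data were examined named a count test as the main test, with limma as the replacement if the table held FPKM without counts. The table held FPKM, so the replacement was used. Values were set to log2(FPKM + 1), genes with at least 1 FPKM in at least 3 libraries were kept (13092 genes), and limma 3.58.1 in R 4.3.3 was fitted with group as the only term, with trend and robust variance moderation, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of genes with low values. Each level is given as a mean ± SD of FPKM over the 3 libraries of a group. Gene lists were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation beside it and with fry, adjusted over the 28 lists. A list's shift is the mean log2 change of its tested members minus that of all other tested genes. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

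The genes named were set by a rule written before the data were examined. It took the 8 largest rises and the 8 largest falls among genes past the threshold whose CPL libraries all lay on one side of all controls, with a mean of at least 5 FPKM in the higher group. It also took up to 4 members of each list past the threshold with a mean of at least 1 FPKM in the higher group, and 22 genes of interest whatever their test. The 28 lists, written from general knowledge, covered NF-κB components, NF-κB targets, senescence secretory factors, senescence arrest, the BCL-2 family, S phase, G2 and mitosis, MYC and nucleolar targets, JAK-STAT targets, interferon response, NRF2, heat shock, the integrated stress response, endoplasmic reticulum chaperones and immediate early genes. They further covered cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, lysosome and autophagy, metallothioneins and histones, and markers of megakaryocyte, erythroid, monocyte, lymphocyte and stem cells. The results of 2 genes of interest and 1 further list are not reported here.

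The depth behind each value was recovered as reads and ranged from 14647923 to 18239562 per library. Replicates of a group were compared on those reads, and each pair differed by more than counting noise (chi-square per degree of freedom between 7.84 and 56.5 over genes with at least 10 reads in both), so each library was counted as 1 sample. The functions were tested on simulated reads for CPL against control, drawn from the real mean levels and depths with 200 changed genes. All genes had the same dispersion of 0.0045, set from the control libraries, so recovery may be overstated for the real data. Among 13064 tested genes, 57.1% of the genes changed 1.5-fold, 89.2% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 10 unchanged genes were called. With a simulated GC bias in the first CPL library, recovery at 1.5-fold was 21.5% over 13054 tested genes, and 56.2% over 13081 after removal of the GC trend, where 20 unchanged genes were called (11.3% of the calls). In 5 simulated draws with the GC bias and no changed gene, at most 2 genes were called after removal of the GC trend.

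Alternatives covered the pseudocount (0.1 and 0.01), the filter (none, or at least 5 FPKM), quantile normalization, a replicate block, and leaving out each library in turn. Those added after seeing the data were removal of the GC trend from each library (loess with span 0.5 on the GC share of the gene's longest transcript in GENCODE 29), alone or with length, with the block or without the first CPL library, 3 rescalings of FPKM, limma-voom on the recovered reads, limma without robust moderation, and a test against a 1.5-fold change. Intervals quoted for list shifts are 95% bootstrap intervals over genes from 2000 draws.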

Results

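Messenger RNA was sequenced from SET-2 cells, an established human megakaryoblastic leukaemia line that carries a mutant JAK2 and is used as a model of the myeloproliferative neoplasms, which are clonal blood disorders driven by JAK-STAT signalling. The 6 libraries fell into 2 groups, 3 libraries labelled as placebo and called control here, and 3 libraries of cells treated with CPL. What CPL is, its dose and the time of treatment were not given in the labels. The series title names cell senescence and NF-κB signalling, and the comparison of CPL with control asks which genes of these and other programmes differed after the treatment. The deposited values were FPKM, fragments scaled to gene length and to the library's read total, for 30735 genes. Reads recovered from these values gave 14647923, 18239562 and 16945860 reads for control replicates 1, 2 and 3, and 15482095, 16175160 and 16062603 for CPL replicates 1, 2 and 3. At these depths 3 reads on a gene of 1 kilobase corresponded to 0.205 FPKM in the shallowest library and 0.165 FPKM in the deepest, a floor that covers counting error only. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

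CPL-treated cells had higher mRNA of 10 of 26 tested NRF2 antioxidant genes and of 3 CXCL chemokines, and lower mRNA of a smaller set of genes. That set included FST and 2 replication helicase subunits, and the calls of these 2 subunits were lost when some single libraries were left out. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214, GRCh38), which encodes haem oxygenase 1 and is a classical target of the oxidative stress factor NRF2, went from 71.2 ± 11.6 FPKM in control to 445 ± 107 FPKM in CPL (SD, n = 3 each), a 6.25-fold higher mean. CXCL8, which encodes the neutrophil chemokine interleukin-8 (chromosome 4, 73740506 to 73743716), went from 5.82 ± 0.33 to 36.6 ± 4.7 FPKM. OSGIN1, an oxidative stress response gene, went from 1.15 ± 0.15 to 8.18 ± 3.61 FPKM, and SQSTM1, which encodes the autophagy receptor p62, from 9.29 ± 0.05 to 35.7 ± 7.2 FPKM. In limma with Benjamini-Hochberg adjustment over 13092 tested genes, 143 genes were higher in CPL and 87 were lower at an adjusted p under 0.05, of which 51 were at least 2-fold higher and 18 at least 2-fold lower on the log2(FPKM + 1) scale.

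**Figure D1:**
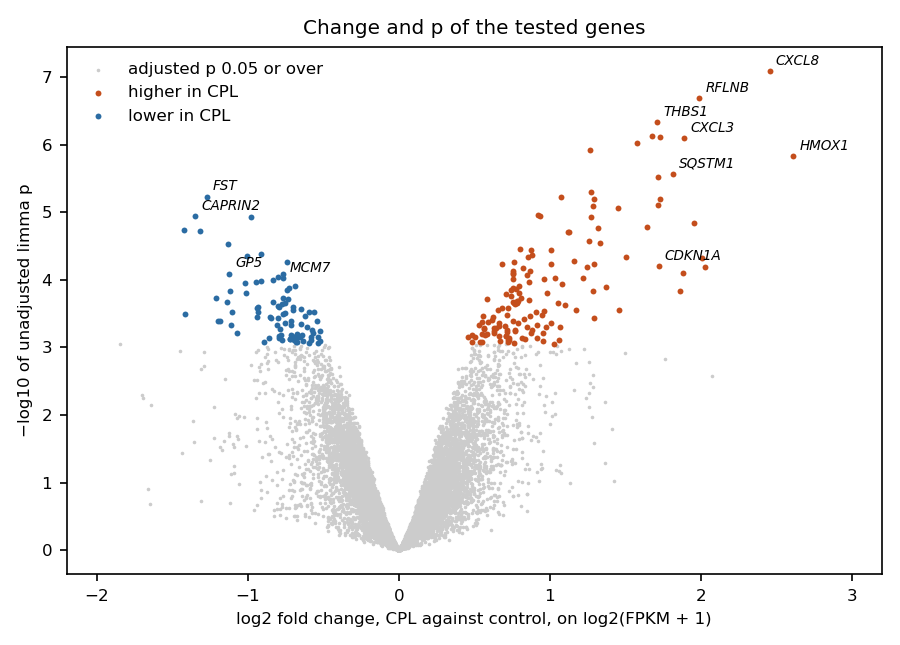
Each point is a tested gene, with its log2 fold change of CPL against control on log2(FPKM + 1) on the horizontal axis and −log10 of its unadjusted limma p on the vertical axis; coloured points passed an adjusted p of 0.05. The 143 genes higher in CPL reach larger changes than the 87 lower genes, with HMOX1 and CXCL8 farthest to the right.

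All 230 called genes had every CPL library on one side of every control library, as did 29.1% of all tested genes, where chance gives 10%. The number of calls moved with single libraries. It was 18, 25 and 24 without control replicate 1, 2 or 3, 703 without CPL replicate 1, 33 without CPL replicate 2 and 200 without CPL replicate 3. CPL replicate 1 stood apart from the other CPL libraries along the GC content of the genes, and with that trend removed from each library 912 genes were higher and 824 lower, including all 230 of the first set. Against the mean of all 6 libraries, which CPL replicate 1 itself moves, other libraries also followed GC. The rank correlation was 0.816 in CPL replicate 1, −0.593 in control replicate 2, −0.565 in CPL replicate 3 and −0.292 to −0.01 in the rest. With the trend removed and CPL replicate 1 left out, 1139 genes were called. Of the 40 named genes that passed the test, 11 passed it in each of the 6 fits that left out 1 library. These were HMOX1, CXCL8, CXCL2, CXCL3, SQSTM1, SLC7A11, RFLNB, GABARAPL1, THBS1, LIF and FST. The other 29 lost the call in at least 1 such fit, with the largest adjusted p (0.204) for GYPC. A lost call need not mean a lost change. Over these fits the log2 change ranged from −0.822 to −0.704 for MCM7 and from 1.729 to 2.268 for OSGIN1.

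The NF-κB target genes that rose were led by chemokines. Of 16 tested members of that list, 5 rose and none fell, and 11 did not pass the test; adjusted over the list alone, 7 rose and 1 fell. CXCL8 was followed by its neighbours on chromosome 4, CXCL2 (74097035 to 74099293), which went from 3.36 ± 0.87 to 15.9 ± 3.4 FPKM, and CXCL3 (74036589 to 74038807), which went from 1.79 ± 0.31 to 9.29 ± 0.90 FPKM. CXCL2 and CXCL3 are close paralogs, so short reads may be divided between them. TNFAIP2 rose from 5.77 ± 0.39 to 12.4 ± 3.2 FPKM. The remaining riser, CD69, an early activation antigen, was chosen after its values were seen and went from 14.6 ± 0.9 to 25.04 ± 4.01 FPKM. The list shifted by 0.52 on the log2 scale against other genes (camera adjusted p = 3.93e-04), with 0.51, 0.50 and 0.55 in CPL replicates 1, 2 and 3. Its call was lost with an estimated correlation (camera adjusted p = 0.0843), although the estimate was −0.022, under the preset 0.01. TNFAIP2 and CD69 lost their calls without any 1 of the 3 controls or CPL replicate 2, CD69 also without CPL replicate 3, with adjusted p up to 0.198.

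Of 17 tested genes that encode NF-κB pathway components and inhibitors, 1 fell, none rose and 16 did not pass the test (camera adjusted p = 0.888); adjusted over the list alone, 1 rose and 2 fell. The one that fell was BIRC3, which encodes the ubiquitin ligase cIAP2 and is itself induced by NF-κB, at 2.95 ± 0.26 FPKM in control and 1.4004 ± 0.112 in CPL (adjusted p = 0.0367, and up to 0.168 when a library other than CPL replicate 1 was left out). The NF-κB subunits NFKB1 and RELA did not pass, at 14.8 ± 0.3 against 12.7 ± 0.6 FPKM (adjusted p = 0.272) and 12.1 ± 0.9 against 15.3 ± 2.5 FPKM (adjusted p = 0.257). After removal of the GC trend NFKB1 was called lower in CPL (limma adjusted p = 0.0459) and RELA was not called (0.0693). In that fit 4 members of the list fell and 1 rose (list shift −0.062, camera adjusted p = 0.495). For the list as deposited, the fry test for change in either direction gave an unadjusted p of 0.00545. That test compares a list with no change, not with other genes. Of the 13092 tested genes, 2558 had an unadjusted limma p under 0.05. Among the lists, the p of this fry test was over 0.05 only for cholesterol synthesis (0.0782), lymphocyte markers (0.116), ribosomal proteins (0.279) and histones (0.44). A low value is thus not particular to the NF-κB components. NFKBIA, which encodes the inhibitor IκBα, was at 10.4 ± 1.0 FPKM in control and 6.75 ± 0.99 in CPL, with an adjusted p of 0.0791, which was 0.0173 without CPL replicate 1, up to 0.277 without another library, and 0.0066 after removal of the GC trend. TNFAIP3, which encodes the inhibitor A20, stayed under the expression filter with 55 to 76 reads per control library and 59 to 71 per CPL library. IL6 had at most 3 reads in any library, and no fold is given for it. IL1B, an abundant NF-κB target, was at 50.6 ± 1.9 FPKM in control and 56.2 ± 2.7 in CPL (adjusted p = 0.404).

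Of 16 tested senescence-associated secretory factors, 5 rose and none fell, and 11 did not pass; adjusted over the list alone, 10 rose and 1 fell. Of the 5, CXCL8, CXCL2 and CXCL3 are shared with the NF-κB targets. MMP14, a membrane metalloprotease, rose from 11.9 ± 1.6 to 26.02 ± 5.16 FPKM. CSF1, the macrophage growth factor, was named after its values were seen and rose from 17.4 ± 1.4 to 35.0 ± 4.9 FPKM. As a set, these factors shifted by 0.66 on the log2 scale (camera adjusted p = 1.75e-06; adjusted p = 0.206 with an estimated correlation), with 0.87 in CPL replicate 1 against 0.60 and 0.52 in replicates 2 and 3. GDF15, a stress cytokine, was at 0.45 ± 0.22 FPKM in control and 1.88 ± 1.35 in CPL and did not pass (adjusted p = 0.18), and its log2 change of 0.91 was 0.55 without CPL replicate 1, which had 3.44 FPKM. MMP14 and CSF1 lost their calls without any 1 of the controls or CPL replicate 2 (adjusted p up to 0.14).

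Of 18 tested senescence arrest regulators 1 rose, none fell and 17 did not pass (camera adjusted p = 0.267). Adjusted over the list alone, 1 rose and 2 fell, and after removal of the GC trend 1 rose and 5 fell over all genes. The list mixes genes that rise in senescence with genes that decline, so a test of 1 direction cannot speak for or against senescence. The fry test for change in either direction gave an unadjusted p of 0.00205. As for the NF-κB components, such a low value was common among the lists and does not set this one apart. CDKN1A, which encodes the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339), rose from 1.98 ± 0.22 to 9.12 ± 2.98 FPKM, a log2 change of 1.72 ± 0.21 (SE, limma adjusted p = 0.0163). It had 78 to 121 reads in the control libraries and 297 to 567 in the CPL libraries, and its adjusted p reached 0.103 when a control or CPL replicate 2 was left out. LMNB1, which encodes lamin B1 and is known to decline in senescent cells, was at 51.8 ± 2.7 FPKM in control and 40.3 ± 0.1 in CPL. Its adjusted p was 0.0987, against 0.0434 without CPL replicate 1, up to 0.312 without another library, and 0.0101 after removal of the GC trend. No value for CDKN2A was found among the deposited genes, so it could not be analysed.

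**Figure D2:**
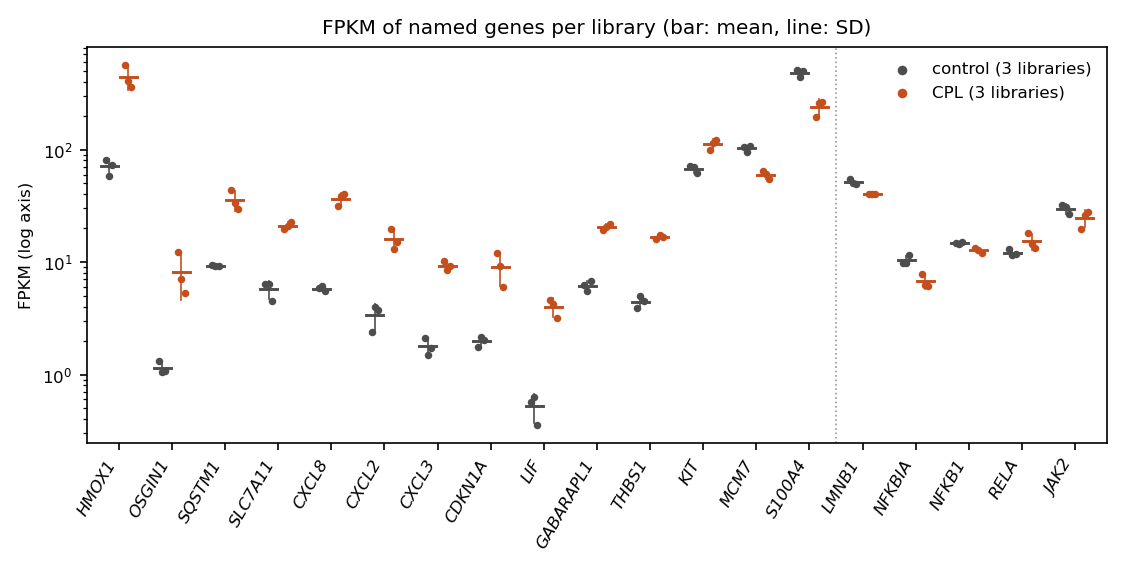
Points give the FPKM of each library on a log axis for 19 named genes, control in grey and CPL in orange, with the mean as a bar and the SD (n = 3) as a line; genes left of the dotted line passed the limma test and those right of it did not. CXCL8 lies at 5.82 FPKM on average in control and 36.6 in CPL, whereas NFKB1 lies at 14.8 and 12.7.

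Of 26 tested members of the NRF2 antioxidant response list 10 rose, none fell and 16 did not pass; adjusted over the list alone, 18 rose and none fell. Next to HMOX1, OSGIN1 and SQSTM1, the cystine transporter gene SLC7A11 rose from 5.73 ± 1.05 to 20.99 ± 1.497 FPKM. This list shifted by 0.80 on the log2 scale against other genes (camera adjusted p = 2.39e-14; adjusted p = 0.0812 with an estimated correlation), by 0.91 in CPL replicate 1, 0.79 in replicate 2 and 0.70 in replicate 3. Without CPL replicate 1, 14 members rose. HMOX1, SQSTM1 and SLC7A11 passed the test without any 1 library, whereas OSGIN1 reached an adjusted p of 0.0987 when a control or CPL replicate 2 was left out.

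Of 30 tested lysosome and autophagy genes, 3 rose, none fell and 27 did not pass; adjusted over the list alone, 13 rose and 1 fell. SQSTM1 is a member of this list and of the NRF2 list. GABARAPL1, an ATG8-family gene of autophagosome formation, rose from 6.18 ± 0.65 to 20.4 ± 1.3 FPKM, and TFE3, a transcription factor of lysosomal genes, from 7.17 ± 0.46 to 12.7 ± 1.2 FPKM. TFE3 lost its call in 4 of the 6 fits that left out 1 library (adjusted p up to 0.136, without a control or CPL replicate 2). Lysosome genes shifted by 0.34 (camera adjusted p = 2.24e-06; adjusted p = 0.0812 with an estimated correlation), with 0.38, 0.33 and 0.32 in the 3 CPL libraries.

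Of 20 tested immediate early and AP-1 genes 4 rose and none fell, and 16 did not pass; adjusted over the list alone, 10 rose. JUN rose from 0.88 ± 0.22 to 3.70 ± 1.33 FPKM, MAFF from 1.47 ± 0.15 to 4.81 ± 1.19, ATF3 from 0.67 ± 0.12 to 2.23 ± 0.40, and FOSL2 from 5.06 ± 0.47 to 8.94 ± 1.30 FPKM. Each of these lost its call when a control or CPL replicate 2 was left out, with adjusted p up to 0.193 for FOSL2, which was also lost without CPL replicate 3. These genes shifted by 0.54 (camera adjusted p = 5.36e-07; adjusted p = 0.28 with an estimated correlation), by 0.84 in CPL replicate 1 and by 0.49 and 0.28 in replicates 2 and 3. Of 26 tested genes of the integrated stress response, the programme of translational stress driven by ATF4, ATF3 and SLC7A11 rose and 24 did not pass; adjusted over the list alone, 13 rose. That list shifted by 0.50 (camera adjusted p = 2.2e-06; adjusted p = 0.212 with an estimated correlation), by 0.72 in CPL replicate 1 and by 0.43 and 0.34 in the others. None of 21 heat shock genes passed (camera adjusted p = 0.149; none adjusted over the list alone). Of 24 endoplasmic reticulum chaperone genes 1 fell and 23 did not pass (camera adjusted p = 0.306; 2 fell adjusted over the list alone). That gene was HSPA5, which encodes BiP, at 210 ± 5 FPKM in control and 136 ± 18 in CPL, and its adjusted p of 0.048 reached 0.2 when a control or CPL replicate 2 was left out.

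**Figure D3:**
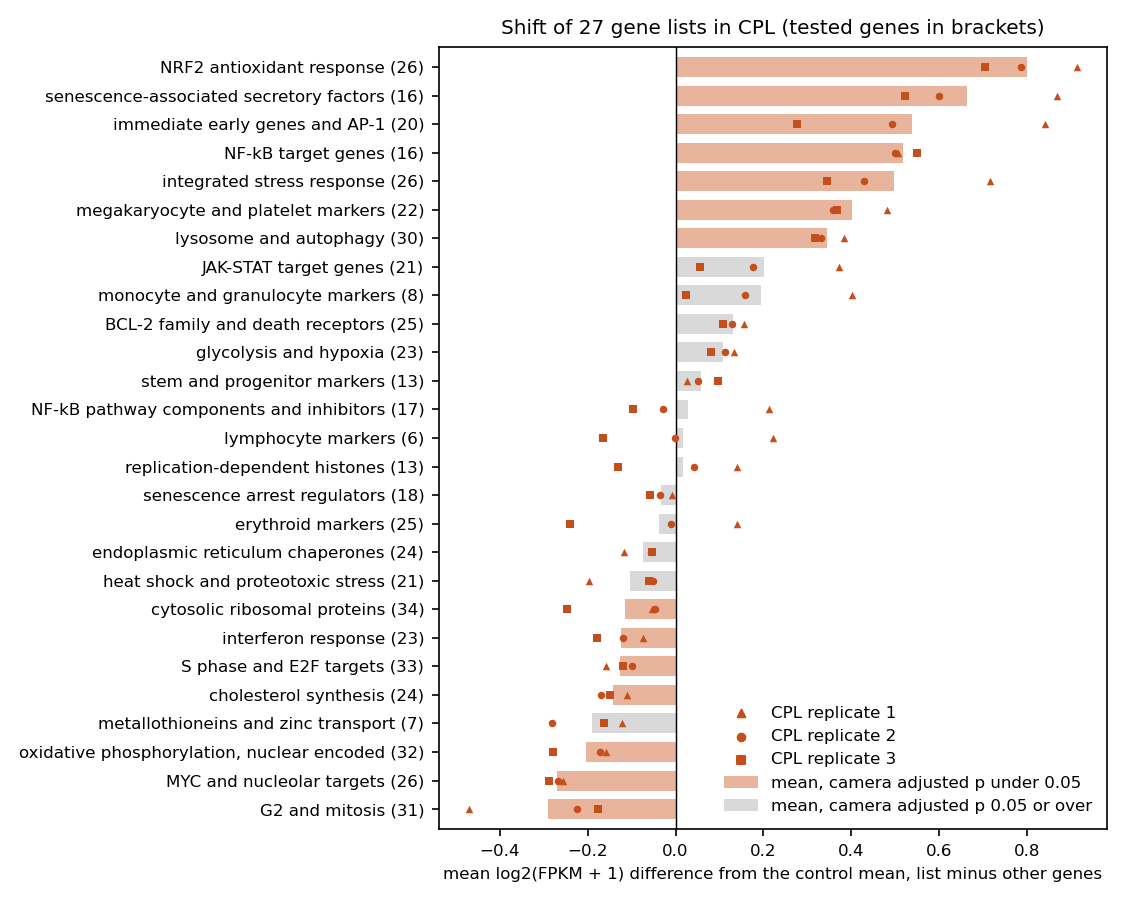
Bars give the mean shift of each of 27 gene lists in CPL, as the difference in log2(FPKM + 1) from the control mean of the list's genes minus that of all other genes, and symbols give the same value for each CPL library. The NRF2 list has the largest rise (0.80) and the G2 and mitosis list the largest fall (−0.29), and CPL replicate 1 lies farthest from 0 in both.

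Of 33 tested S phase and E2F target genes 2 fell, none rose and 31 did not pass, with the same 2 adjusted over the list alone. These encode subunits of the replicative helicase, and both lost the call without any 1 control or CPL replicate 2 (adjusted p up to 0.174), MCM3 also without CPL replicate 3. MCM7 went from 103 ± 6 to 60.005 ± 4.98 FPKM and MCM3 from 190 ± 8 to 128 ± 5 FPKM. As a list they shifted by −0.13 (camera adjusted p = 0.0184; adjusted p = 0.171 with an estimated correlation), and its call was lost without control replicate 3 (adjusted p = 0.0521) or CPL replicate 3 (0.0664). None of 31 G2 and mitosis genes passed on its own, nor adjusted over the list alone, but 28 of the 31 had a negative change and 18 had every CPL library below every control library. The G2 and mitosis list shifted by −0.29 (camera adjusted p = 5.36e-07; adjusted p = 0.206 with an estimated correlation), by −0.47 in CPL replicate 1 and by −0.23 and −0.18 in the others. MKI67, the proliferation antigen Ki-67, was at 15.7 ± 0.8 FPKM in control and 12.9 ± 1.0 in CPL (adjusted p = 0.223). Of 26 MYC and nucleolar targets 1 fell and 25 did not pass; adjusted over the list alone, 5 fell. UTP20, a ribosome biogenesis factor, went from 9.53 ± 1.13 to 5.46 ± 0.70 FPKM, and its adjusted p of 0.0462 reached 0.183 when a control or CPL replicate 2 was left out. Together these targets shifted by −0.27 (camera adjusted p = 6.02e-06; adjusted p = 0.0812 with an estimated correlation). MYC itself was at 149 ± 15 FPKM in control and 192 ± 38 in CPL (adjusted p = 0.272).

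None of 32 nuclear-encoded oxidative phosphorylation genes passed over all genes, and adjusted over the list alone 7 fell; the list shifted by −0.20 (camera adjusted p = 8.36e-05; adjusted p = 0.212 with an estimated correlation). None of 34 cytosolic ribosomal protein genes passed by either adjustment, and the list's shift of −0.12 (camera adjusted p = 0.0386; adjusted p = 0.65 with an estimated correlation) was −0.043 without control replicate 3 (adjusted p = 0.451) and −0.05 without CPL replicate 3 (adjusted p = 0.669). None of 24 cholesterol synthesis genes passed by either adjustment, with a shift of −0.14 (camera adjusted p = 0.0386; adjusted p = 0.206 with an estimated correlation). The cholesterol call was lost without control replicate 1 (adjusted p = 0.0612) or 3 (0.0992) and without CPL replicate 2 (0.106) or 3 (0.0903). Of 23 glycolysis and hypoxia genes 1 rose and 22 did not pass (camera adjusted p = 0.187; 1 rose and 1 fell adjusted over the list alone). The riser was SLC2A1, which encodes the glucose transporter GLUT1, at 51.9 ± 2.0 FPKM in control and 145 ± 26 in CPL, with an adjusted p of 0.00596, or 0.0576 without control replicate 1. Of 7 metallothionein and zinc transport genes, the zinc exporter gene SLC30A1 fell from 10.2 ± 0.9 to 5.46 ± 0.76 FPKM and 6 did not pass (its adjusted p reached 0.147 without a control or CPL replicate 2; list camera adjusted p = 0.233; 2 fell adjusted over the list alone). The median change of that list was 0.04 and its mean −0.18. None of 13 histone genes passed by either adjustment (camera adjusted p = 0.888, direction down, with a positive median of 0.03 and mean of 0.02). Replication-dependent histone mRNAs mostly lack a poly(A) tail and are poorly captured by oligo(dT) selection. The list also holds replication-independent histone genes, to which this does not apply.

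Of 21 tested JAK-STAT target genes 2 rose and none fell, the same 2 adjusted over the list alone, and 19 did not pass. The list's shift of 0.20 did not pass (camera adjusted p = 0.149) and was 0.12 without CPL replicate 1 (adjusted p = 0.42). The 2 that rose were CDKN1A and LIF, the gene of the cytokine leukaemia inhibitory factor, which went from 0.52 ± 0.15 to 4.01 ± 0.74 FPKM. JAK2 was at 29.8 ± 2.9 FPKM in control and 24.6 ± 4.3 in CPL (adjusted p = 0.349), STAT5A at 54.0 ± 1.6 and 54.0 ± 6.6 (adjusted p = 0.981), and the STAT5 target PIM1 at 129 ± 7 and 147 ± 21 FPKM (adjusted p = 0.459). None of 25 genes of the BCL-2 family and death receptors passed (camera adjusted p = 0.0689, and 2 rose adjusted over the list alone). This list mixes genes that promote and that oppose cell death, so a test of 1 direction cannot speak for either. The fry test for change in either direction gave an unadjusted p of 0.00433, a low value of the kind that most lists had. BCL2L1 was at 22.6 ± 2.3 and 26.4 ± 3.1 FPKM (adjusted p = 0.379) and MCL1 at 65.9 ± 2.3 and 64.7 ± 4.3 FPKM (adjusted p = 0.904). BCL2 stayed under the expression filter with 110 to 136 reads per library. Of 23 interferon response genes 1 fell and 22 did not pass; adjusted over the list alone, 6 fell. USP18, an interferon-induced protease, went from 3.12 ± 0.28 to 1.41 ± 0.08 FPKM, with an adjusted p of up to 0.147 when a library other than CPL replicate 1 was left out. The interferon list's shift of −0.12 (camera adjusted p = 0.0469; adjusted p = 0.206 with an estimated correlation) turned to 0.067 when only genes with at least 5 FPKM were tested (adjusted p = 0.63). That call was also lost without control replicate 3 (adjusted p = 0.0868) and without CPL replicate 2 (0.0659) or 3 (0.196).

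Of 22 tested megakaryocyte and platelet markers 3 rose, none fell and 19 did not pass; adjusted over the list alone, 8 rose. THBS1, the gene of the platelet granule protein thrombospondin 1, went from 4.45 ± 0.50 to 16.8 ± 0.7 FPKM, RAB27B, a granule secretion GTPase, from 15.2 ± 1.5 to 34.2 ± 7.9 FPKM, and SELP, the gene of P-selectin, from 1.87 ± 0.45 to 4.22 ± 0.29 FPKM. The markers shifted by 0.40 (camera adjusted p = 2.2e-06; adjusted p = 0.0843 with an estimated correlation), by 0.48 in CPL replicate 1 and by 0.36 and 0.37 in the others. RAB27B and SELP lost their calls when a control or CPL replicate 2 was left out, and SELP also without CPL replicate 3 (adjusted p up to 0.156). Of 25 erythroid markers 1 fell and 24 did not pass (camera adjusted p = 0.554; 3 fell adjusted over the list alone). GYPC, the gene of glycophorin C, fell from 26.1 ± 3.0 to 15.9 ± 1.7 FPKM, and its call was lost when a library other than CPL replicate 1 was left out (adjusted p up to 0.204). Of 13 stem and progenitor markers 1 rose and 12 did not pass (camera adjusted p = 0.655; 2 rose and 2 fell adjusted over the list alone). KIT, the stem cell factor receptor gene, went from 67.4 ± 5.2 to 112 ± 12 FPKM, and its adjusted p of 0.0334 reached 0.157 when a library other than CPL replicate 1 was left out. None of 8 monocyte and granulocyte markers (camera adjusted p = 0.736; 2 rose and 2 fell adjusted over the list alone) and none of 6 lymphocyte markers (camera adjusted p = 0.943; none adjusted over the list alone) passed.

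Of the other genes that the naming rule took for their size of change, RFLNB, which encodes refilin B, rose from 13.1 ± 1.4 to 55.0 ± 3.9 FPKM, and CEP170B from 0.97 ± 0.07 to 7.29 ± 3.197 FPKM. The falls that it took included CAPRIN2, from 22.97 ± 2.62 to 8.41 ± 1.12 FPKM, and FST, which encodes the activin antagonist follistatin, from 7.83 ± 0.82 to 2.64 ± 0.20 FPKM. GP5, the gene of platelet glycoprotein V, fell from 6.96 ± 1.09 to 2.64 ± 0.45 FPKM while THBS1 and SELP rose. AQP3, an aquaglyceroporin gene, fell from 17.7 ± 2.5 to 7.62 ± 1.47 FPKM, and S100A4, a calcium-binding protein gene, from 483 ± 37 to 241 ± 41 FPKM. The long noncoding gene AP001628.1 fell from 44.7 ± 7.2 to 19.8 ± 3.7 FPKM. BX293535.1 fell from 7.44 ± 2.01 to 2.16 ± 0.74 FPKM and is annotated as antisense, so its reads cannot be told apart from those of a gene on the other strand where counting does not use strand. TRAV8-5, a T cell receptor pseudogene whose reads may come from its relatives, fell from 5.91 ± 0.96 to 2.32 ± 0.70 FPKM. CEP170B lost its call when a control was left out (adjusted p up to 0.0963), CAPRIN2 without control replicate 1 or 2 (up to 0.0564), and GP5, AQP3, S100A4, AP001628.1 and TRAV8-5 without any 1 control or CPL replicate 2 (up to 0.176). BX293535.1 kept its call only without CPL replicate 1 (up to 0.15 otherwise).

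Of the 28 lists, 14 passed camera with its preset correlation of 0.01, 7 upwards and 7 downwards, and none passed at an adjusted p of 0.05 with an estimated correlation, where the lowest was 0.0812 and 6 lists had an unadjusted p under 0.05. Among the 14 lists that passed, the estimated correlation ran from −0.028 (interferon response) to 0.525 (immediate early genes). It was −0.022 for NF-κB targets and −0.017 for MYC and nucleolar targets, under the preset 0.01. A higher correlation was thus not what removed those calls. The estimate was above the preset for the NRF2 list (0.101) and the secretory factors (0.254). With an estimated correlation camera also uses the few residual degrees of freedom of 6 libraries, which by itself raises p. For lists with a higher correlation, the parts of these 2 changes in a lost call were not separated. The directional test fry, which does not compare a list with other genes, passed 18 lists. The library that stood apart, CPL replicate 1, correlated with CPL replicates 2 and 3 at r = 0.964 and 0.948 over genes, against 0.983 between those and 0.979 to 0.981 between controls. Across genes, which are not independent replicates, its log2 difference from the mean of the other CPL libraries rose with transcript GC, from a median of −0.35 in the lowest of 5 equal groups of protein-coding genes by GC to 0.56 in the highest.

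**Figure D4:**
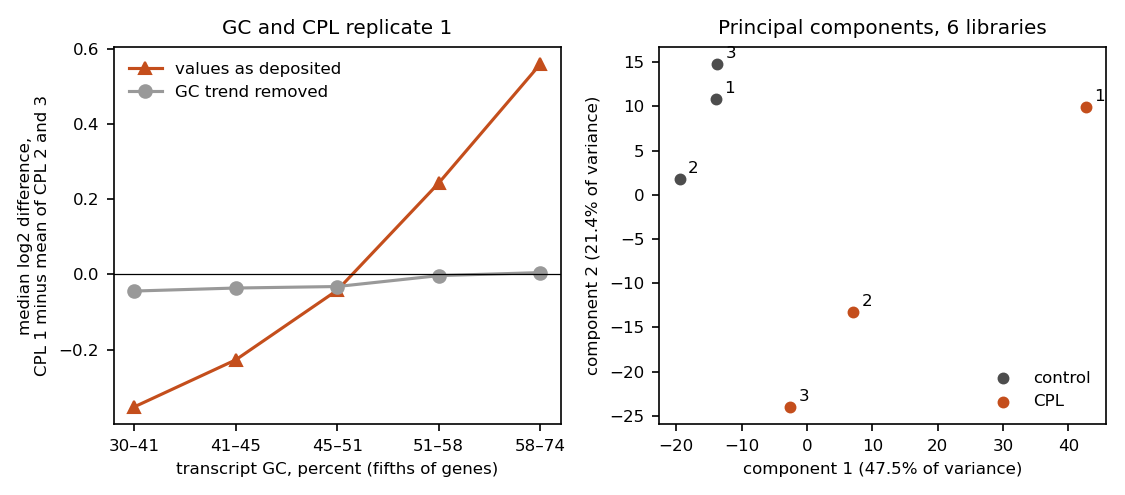
Left, the median log2 difference of CPL replicate 1 from the mean of CPL replicates 2 and 3 in 5 equal groups of protein-coding genes by transcript GC, as deposited and after removal of the GC trend; right, the 6 libraries on the first 2 principal components of log2(FPKM + 1), numbered by replicate. CPL replicate 1 lies at 42.6 on the first component (47.5% of the variance), against 7.04 and −2.53 for the other CPL libraries and −19.5 to −13.7 for the controls.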

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

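The alternatives that removed the GC or length trend, rescaled FPKM, used voom, dropped robust moderation or tested against a 1.5-fold change were chosen after seeing the data. The counts of 143 genes higher and 87 lower in CPL stayed within 1.5 times under both pseudocounts, the filter at 5 FPKM, quantile normalization, the 3 rescalings and limma without robust moderation. They moved to 21 and 4 with no filter on FPKM, where 30735 genes were tested, to 48 and 15 with the replicate number as a block, and to 319 and 185 with voom on recovered reads. With the block, 18 of the 40 named genes that had passed lost their call. The column names share a prefix for equal replicate numbers, but the labels state no pairing. Deviations from the group mean correlated at 0.084, 0.088 and −0.168 between control and CPL replicates 1, 2 and 3 of equal number. For unequal numbers they correlated at −0.229 to 0.222, so equal numbers did not match more closely in these values. Against a 1.5-fold change 10 genes were higher and 0 lower, since that test asks for more than a difference. Leaving out each library in turn gave 17 to 364 higher and 1 to 339 lower, the lowest without control replicate 1 and the highest without CPL replicate 1.

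With the GC trend removed the counts were 912 higher and 824 lower, with GC and length trends removed 904 and 893, with the GC trend removed and without the first CPL library 612 and 527, and with the GC trend removed and the block 550 and 521. The share of higher genes among the calls was 62.2% as reported, 52.5% with the GC trend removed, 50.3% with GC and length removed and 71.3% with totals that leave out the 50 highest genes. The cause of these moves was not tested.

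With an estimated correlation the shifts of the NF-κB target list (0.518, adjusted p = 0.0843), the secretory factors (0.663, adjusted p = 0.206) and the NRF2 list (0.8, adjusted p = 0.0812) are the same values without a call. With no filter on FPKM the NF-κB target shift was 0.275 and that of the secretory factors 0.337, with more genes tested and both still called (adjusted p = 0.00695 and 8.21e-05). By fry, which tests a list against no change and not against other genes, 5 lists gained a call and 1 lost it. Those gained included senescence arrest (adjusted p = 0.0386), whose shift against other genes of −0.033 did not pass camera (0.267), the BCL-2 family (0.00425), endoplasmic reticulum chaperones (0.0125) and glycolysis (0.0474). The ribosomal proteins lost it (0.396). The interferon list turned from −0.124 to 0.067 among genes with at least 5 FPKM (adjusted p = 0.63), where fewer genes were tested. Of 644 list results under alternatives, 578 kept direction and side of the threshold, 18 with no call in either fit changed sign, 38 lost a call, 9 gained one and 1 was the interferon reversal. Of 1202 results of named genes 959 kept both, 25 with no call in either fit changed sign, 205 lost a call and 13 gained one. The planned tests on the authors' counts were not run, since the table holds FPKM; voom used reads recovered from it. Depth limits genes such as IL6, with at most 3 reads in a library.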

Other observations

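The test of GC content in CPL replicate 1 was chosen after the result was seen, as were the removal of the GC trend, the response ratios of CPL replicates 2 and 3, the proteasome list and the genes of the next paragraphs. Of 31 constitutive subunit genes of the 26S proteasome, the main protease of ubiquitin-tagged proteins, 28 were higher in CPL and 3 passed the test: PSMC4 rose from 70.1 ± 4.9 to 119 ± 13 FPKM, PSMD2 from 72.1 ± 1.5 to 109 ± 5 FPKM and PSMD11 from 32.8 ± 0.6 to 45.4 ± 0.2 FPKM (SD, n = 3, adjusted p from 0.0267 to 0.0465 in limma). Among the 27 subunits not seen before the list was made, 24 were higher with none past the test, and their mean shift was 0.218 on the log2 scale (95% interval over genes 0.157 to 0.273, limma camera adjusted p = 6.24e-06 over the 2 set tests of this part, and p = 0.0719 with an estimated correlation). After removal of the GC trend 26 of the 27 were higher and 7 rose, with a shift of 0.264 (camera p = 5.69e-08, and p = 0.116 with an estimated correlation). The immunoproteasome subunit gene PSMB9 went the other way, from 19.7 ± 1.4 to 11.4 ± 0.8 FPKM (adjusted p = 0.0228). PSMC4, PSMD2, PSMD11 and PSMB9 lost their calls without any 1 control or CPL replicate 2, and PSMD11 also without CPL replicate 3 (adjusted p up to 0.202). A joint rise of the constitutive subunits may thus be part of the response to CPL, as a hypothesis found in these data.

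A few other genes are given as single values, chosen because they rose. SLC40A1, which encodes the iron exporter ferroportin, rose from 165 ± 9 to 279 ± 22 FPKM (adjusted p = 0.019), and ALAS1, a haem synthesis enzyme, from 25.97 ± 1.22 to 44.8 ± 2.5 FPKM (adjusted p = 0.0156). FTL, a ferritin subunit gene with many pseudogenes and a member of the NRF2 list, rose from 2083 ± 150 to 6587 ± 1399 FPKM (adjusted p = 0.00821). CYP1A1 and CYP1B1, known targets of the aryl hydrocarbon receptor, rose from 0.78 ± 0.10 to 3.27 ± 0.72 FPKM (adjusted p = 0.0165) and from 4.42 ± 0.91 to 10.4 ± 1.0 FPKM (adjusted p = 0.0209). Each of these 5 lost its call without any 1 control (adjusted p up to 0.12), and all but FTL also without CPL replicate 2.

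CPL replicate 1 stood apart from the other CPL libraries. Over protein-coding genes, the rank correlation of transcript GC with its deviation from them was 0.87, and removal of the trend took away 52.7% of the variance of that deviation, so GC bias of this library is a candidate explanation for part of it. After removal CPL replicate 1 still lay apart on the first 2 principal components, at 24.6 and 18.5. CPL replicate 2 lay at 12.8 and −8.54 and CPL replicate 3 at 12.9 and −16.7. For gene length or degradation, the rank correlation was −0.218 before and 0.004 after removal of the GC trend, which argues against a length effect apart from GC. For a stronger response in that culture, the median ratio of its corrected change to that of the other CPL libraries was 1.003 (95% interval 0.978 to 1.024) over 1139 genes called without it, under the 1.2 set in advance for this explanation. A stronger response stays open, since the same ratio was 0.896 (0.878 to 0.915) for CPL replicate 2 and 0.894 (0.872 to 0.928) for CPL replicate 3, each over genes called without it. Nor can the ratio see a response that follows GC, as that trend was removed first. After removal, list shifts in CPL replicates 1, 2 and 3 were 0.567, 0.403 and 0.363 for the integrated stress response. They were −0.314, −0.198 and −0.194 for G2 and mitosis, but 0.304, 0.316 and 0.329 for lysosome genes.

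The rise of the NRF2 list kept 97.7% of its shift after removal of the GC trend and 93% without CPL replicate 1, so the tables argue against GC bias and against this library as its whole cause. In the NF-κB target list, a rise of the list as a whole was set against a rise of its chemokines: the mean shift was 2.09 for CXCL8, CXCL2 and CXCL3. The 13 other members had a mean shift of 0.155, upwards, with a 95% interval over genes of −0.045 to 0.371 (limma camera adjusted p = 0.0821). CXCL1, the other chemokine set in advance, was under the expression filter and not tested. The rise may therefore rest mainly on a few chemokine genes, and a smaller rise of the others stays open. Of the list's 16 tested members, 9 had every CPL library above every control library and 1 had every CPL library below.

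Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, itself, with 230 genes against 0 for the highest other, and the same 1 of 10 held after removal of the GC trend, with 1736 against 0. Splits are too few for a share under 0.05.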
